A study of Gallus gallus with 22 samples.

How the data were processed

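The series holds RNA sequencing of the bursa of Fabricius, the organ in which B cells of birds mature, from male commercial broiler chickens aged 4 weeks. Per the labels, birds were mock-challenged or challenged with Avian Pathogenic Escherichia coli O1, and the challenged birds carry the phenotype resistant or susceptible; how the phenotype was scored is not given in the sources used here. Libraries came from day 1 and day 5 after the challenge, which gives 6 groups. Here 22 libraries were analysed, 3 mock, 4 resistant and 4 susceptible on each day; further libraries that the labels describe were not analysed here. The labels do not state that each library came from a separate bird, so p-values measure the spread between these libraries.

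Per the labels' protocols, libraries were made with the Illumina TruSeq RNA version 2 kit from poly-A selected RNA and were sequenced on a HiSeq 2000, with 1 library of each group in a lane. No label says which library was in which lane. Per the submitters' processing notes, the tools were TopHat2 2.0.9, Bowtie2 2.1.0, HTSeq 0.5.4p3, edgeR 3.0.8 and R 2.15.3. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Each deposited file holds raw counts, whole numbers of reads per Ensembl transcript ID that the authors did not normalize. There were 17954 IDs and 5 summary rows per file. The summary rows, which name no transcript, were kept out of library sizes and tests. They held 29.7 to 36.7% of all counts of a library, with 18.0 to 25.5% in the row for reads assigned to no feature, 4.81 to 5.73% in the row for ambiguous reads and 5.27 to 6.35% in the row for reads with more than 1 alignment. Reads that fit more than 1 feature are in the ambiguous row, and those with more than 1 alignment in a separate row. Counts of overlapping, paralogous or antisense features are therefore uncertain.

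The deposited files do not pair IDs with gene names, and the reference table of gene names (assembly GRCg7b) has 0 rows with an Ensembl ID. No ID was therefore named, and the 24 gene lists fixed before the data were examined, with their set tests, and the rule for named genes could not be applied as written. The rule was kept without its condition on a symbol: adjusted p under 0.05, mean log2 CPM of at least 1, groups whose CPM ranges do not overlap, and the largest fold changes. It was limited to 2 IDs per direction, and IDs are printed for 1 comparison only. That change was made after the files were seen.

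Counts were analysed in R 4.3.3 with edgeR 4.0.16. Transcripts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 12651. Library sizes were scaled by TMM. All 6 groups were fitted together with robust quasi-likelihood (16 residual degrees of freedom), and 12 contrasts were tested: 6 within a day, 3 between days and 3 differences of a within-day contrast between the days. Tests were two-sided, with Benjamini-Hochberg adjustment over transcripts and a threshold of 0.05. The common biological coefficient of variation was 0.339. Standard errors of log2 fold changes follow from the quasi-likelihood F. Values per library are CPM on the TMM-scaled totals, and log2 CPM had a prior count of 2. Single measures were compared by exact permutation of libraries, adjusted over the 9 pairs of groups tested for a measure.

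Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, limma-voom with sample quality weights (limma 3.58.1), no low-count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of 5 CPM), the replicate number as a block, a fit of the compared groups only, and leaving out each library in turn. Others were added after seeing the data: thinning every library to the smallest total, and removing the 10 transcripts with the highest mean CPM over all libraries. Also added then were removing mock replicate 2 and susceptible replicate 2 of day 5, and a covariate for a gradient among birds. Those libraries were picked because they lay at the ends of the first principal component, so that removal selects on the outcome. The gradient was the first principal component of deviations from group means, with loadings taken only from groups not compared. For susceptible against mock birds on day 5 it came from 15 libraries and held 39.3% of their within-group variance. Every library, also a compared one, was scored from its own log2 CPM and these loadings. The sign was set so that susceptible libraries of both days scored above mock libraries on average, so the compared libraries helped to set it.

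The count test was tested on simulated data with 12651 transcripts. For susceptible against mock birds on day 5, 24% of transcripts changed 2-fold and 74% of those changed 4-fold were recovered, with 1 unchanged transcript called. For susceptible against resistant birds on day 5 the shares were 39% and 84%, with 5 unchanged called, and for susceptible against mock birds on day 1 they were 30% and 80%, with 6. These simulated transcripts were drawn independently of each other, without a gradient among libraries. The numbers of unchanged transcripts called therefore do not give the rate of false calls in the real libraries. In each simulation 100 transcripts changed 2-fold and 100 changed 4-fold, and 99 were called for susceptible against mock birds on day 5. With 3426 real calls the adjusted threshold admits larger unadjusted p-values, so the shares recovered may understate the sensitivity of that test. The gradient was tested on 20 simulated draws of 2000 genes at each of 2 noise levels. The median correlation of true and recovered loadings was 0.964 at a noise SD of 1 and 0.987 at 0.5. An earlier version of this test had a fixed limit that 1 draw at the larger noise missed; it was replaced by the value expected from the spread of the simulated scores (medians 0.965 and 0.987). The simulation of shared controls was rewritten once after its first output was seen, because that version held the mock libraries fixed and so carried none of their sampling error. It draws transcripts independently of each other. The sets of smallest p in that simulation, and the division of the mock libraries, which used mean log2 CPM, were added after the results were seen.

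Reads on transcripts ranged from 7199071 to 18482076 per library, except mock replicate 1 of day 1 with 60957310. No pair of libraries of a group was identical, and the chi-square per degree of freedom of their counts was 14.8 at the lowest, far above sampling noise.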

Results

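The transcriptome of the bursa of Fabricius was measured in 22 libraries of mock-challenged, resistant and susceptible broilers, 1 and 5 days after challenge with Avian Pathogenic Escherichia coli O1, a bacterium that causes disease outside the gut of poultry. Each day had 3 mock, 4 resistant and 4 susceptible libraries. Reads on transcripts had a median of 12460408 per library and ranged from 7199071 to 18482076, apart from mock replicate 1 of day 1 with 60957310. Features are Ensembl transcript IDs, which the files do not pair with gene names, so groups of transcripts are described by direction, abundance and levels. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12651 transcripts.

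The first question was how the bursa of susceptible birds differed from that of mock birds. On day 5, 3426 transcripts differed, 1717 of them higher and 1709 lower in susceptible birds. The median log2 fold change was 1.54 among the higher and -0.86 among the lower transcripts. More than 2-fold differences were found for 1398 of the higher and 638 of the lower transcripts, and more than 4-fold differences for 441 and 35. At an unadjusted p under 0.05 there were 5422 transcripts, 42.9% of those tested. The values of the groups did not overlap for 4542 transcripts (35.9%), where splits of the libraries give 5.71% on average. Transcripts can move together, so a single split may lie far from that average, and the spread over splits was not computed.

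**Figure D1:**
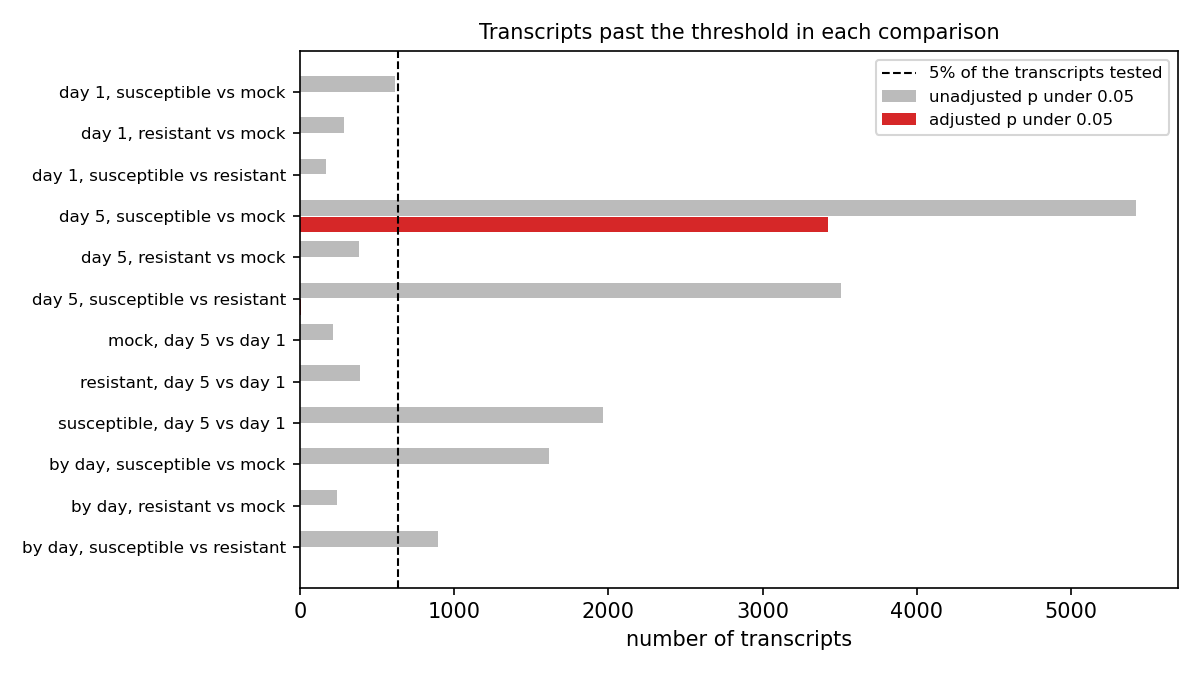
Number of transcripts (horizontal axis) past an unadjusted p of 0.05 (grey bars) and an adjusted p of 0.05 (red bars) in each of the 12 comparisons, with a dashed line at 5% of the 12651 transcripts tested. Susceptible against mock birds on day 5 had 3426 transcripts past the adjusted threshold and susceptible against resistant birds on day 5 had 4, too few to be visible as a bar.

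This count rested on few libraries. It was 655 without mock replicate 2, 1129 without mock replicate 3 and 1063 without susceptible replicate 2 of day 5; without both mock replicate 2 and susceptible replicate 2 it was 0, with 2598 at an unadjusted p under 0.05. With the gradient among birds as a covariate it was 178, of which 148 were among the 3426, and limma-voom with sample quality weights gave 6877. Those weights were 0.641, 0.423 and 7.83 for mock replicates 1, 2 and 3 of day 5, so its mock mean rested largely on replicate 3.

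The directions differed by abundance. Of the 1609 transcripts with a mean log2 CPM over 7, 653 were lower (40.6%) and 46 higher in susceptible birds on day 5. Of the 2257 transcripts with a mean log2 CPM of 1 to 3, 514 were higher (22.8%) and 52 lower. The 10 most abundant transcripts of each library, which may differ between libraries, took 8.22% ± 0.72 of reads in susceptible birds (SD, n = 4). They took 15.7% ± 4.98 in mock (n = 3) and 16.7% ± 7.63 in resistant birds (n = 4). The balance of directions depends on the scaling, and RLE gave 1633 higher and 1845 lower. How far low counts limit the calling of decreases was not tested. The higher transcripts together took 7.68% ± 1.85 of reads on transcripts in susceptible birds (SD, n = 4), 2.47% ± 0.77 in mock birds (n = 3) and 3.42% ± 0.72 in resistant birds (n = 4). The lower transcripts took 28.1% ± 2.87 in susceptible, 40.8% ± 4.80 in mock and 37.4% ± 3.18 in resistant birds. The transcripts were chosen by the comparison of susceptible with mock birds, so these shares do not test that difference again. Among the higher transcripts, 2 had no count in any mock library of day 5, and no fold is given for them.

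**Figure D2:**
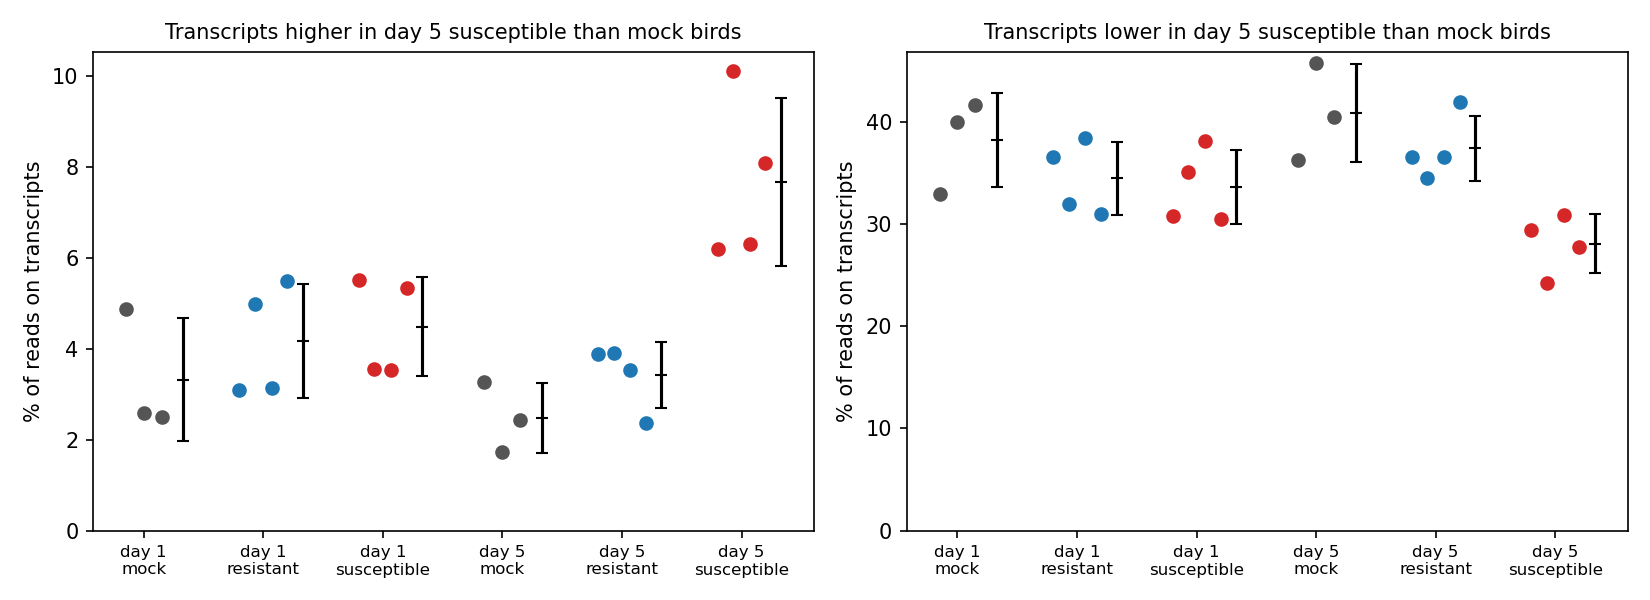
Share of reads on transcripts (vertical axes, percent) taken per library by the 1717 transcripts higher (left) and the 1709 lower (right) in susceptible than in mock birds on day 5, with points for libraries and bars for the mean and SD of each group. Mock replicate 1 of day 1, the first point of the first group, lies apart from the other mock libraries of that day in both panels.

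The largest increases under the naming rule were in ENSGALT00000025427 and ENSGALT00000015790. ENSGALT00000025427 had a log2 fold change of 6.25 ± 1.71 (SE, adjusted p = 0.0163), but susceptible replicate 4 alone stood at 287 CPM, while the other susceptible libraries of day 5 had at most 5.49 CPM; without that replicate the log2 fold change was 1.73 and the adjusted p was 0.204. ENSGALT00000015790 was at 106 ± 92.5 CPM in susceptible (SD, n = 4) and 2.63 ± 0.23 CPM in mock birds (n = 3), a log2 fold change of 5.34 ± 1.05 (SE, adjusted p = 0.00725). The largest decreases were in ENSGALT00000002370 and ENSGALT00000036163. ENSGALT00000002370 was at 1.48 ± 0.88 CPM in susceptible and 29.9 ± 11.9 CPM in mock birds, a log2 fold change of -4.31 ± 0.88 (SE, adjusted p = 0.00746). ENSGALT00000036163 was at 11.5 ± 11.2 CPM in susceptible and 134 ± 41.5 CPM in mock birds, a log2 fold change of -3.53 ± 0.63 (SE, adjusted p = 0.0062). Without mock replicate 2 and susceptible replicate 2 none of these 4 passed the threshold (adjusted p of 0.116 to 0.124), with log2 fold changes, in the order above, of 6.56 ± 2.01, 4.67 ± 1.20, -3.77 ± 1.02 and -3.01 ± 0.69 (SE). With the gradient as a covariate they were 5.76 ± 1.97, 4.55 ± 1.24 and -3.80 ± 1.03 (SE, adjusted p = 0.097, 0.062 and 0.0593), and -2.69 ± 0.64 for ENSGALT00000036163, which still passed (adjusted p = 0.0457).

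**Figure D3:**
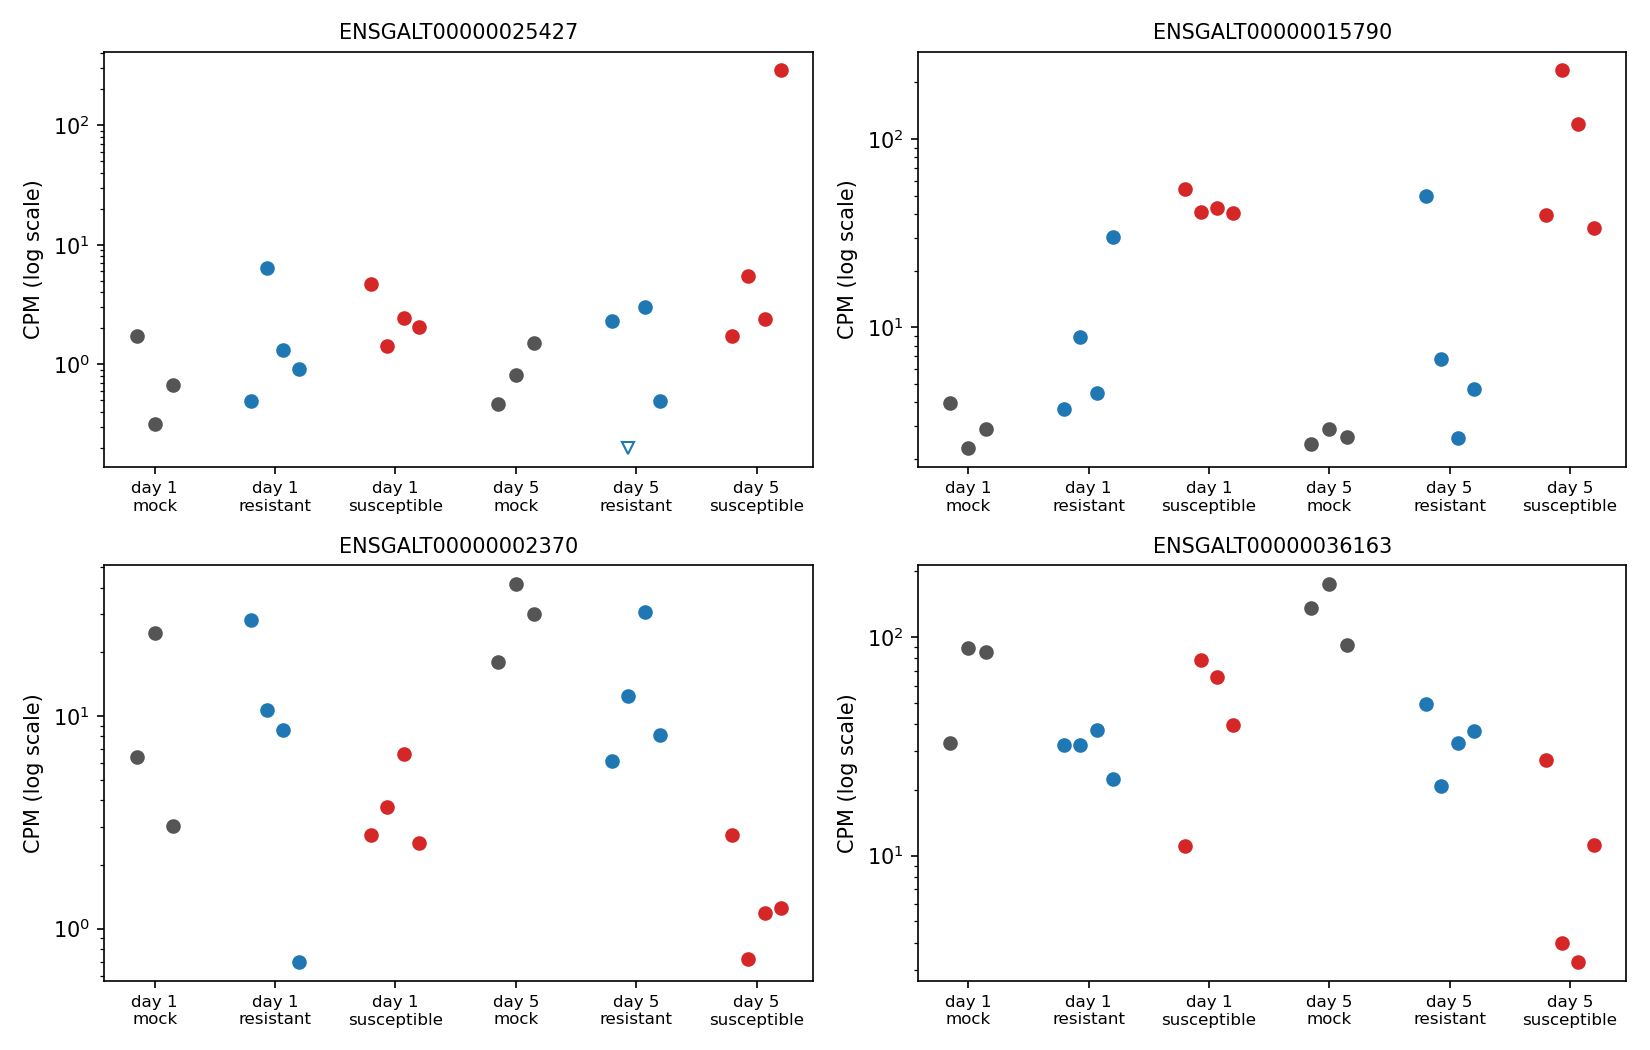
CPM per library (vertical axes, log scale) of the 4 named transcripts in the 6 groups, 1 point per library; the open triangle marks a resistant library of day 5 at 0 CPM. ENSGALT00000015790 lies above every mock library in all susceptible libraries of both days, and the mean of ENSGALT00000025427 on day 5 is set by 1 library at 287 CPM.

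On day 1, no transcript differed between susceptible and mock birds at the adjusted threshold in edgeR, with 614 at an unadjusted p under 0.05 (4.85%) and a smallest adjusted p of 0.167. DESeq2 called 24 and limma-voom with sample quality weights 1210. Its weights were 0.238, 2.62 and 1.17 for mock replicates 1, 2 and 3 of day 1, so replicate 1 counted little. ENSGALT00000015790 was at 44.7 ± 6.36 CPM in susceptible (SD, n = 4) and 3.04 ± 0.85 CPM in mock birds (n = 3) on day 1, a log2 fold change of 3.84 ± 0.97 (SE) with an adjusted p of 0.437 that did not pass. The transcripts called higher on day 5 had a median log2 fold change of 0.30 on day 1, with 83.3% above 0, and those called lower had -0.25, with 91.2% below 0. Across transcripts, which are not independent replicates, the fold changes of both days correlated with r = 0.50, and 13 of 35 relabelings of the day 1 libraries gave a correlation as far from 0 (exact permutation p = 0.371).

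The comparison of resistant with mock birds asked the same of challenged birds with the phenotype label resistant. No transcript passed in edgeR on day 1, with 286 at an unadjusted p under 0.05, or on day 5, with 382. DESeq2 also called 0 on both days, and limma-voom with sample quality weights called 1139 on day 1 and 716 on day 5. Both limma-voom counts rest on the unequal weights of the mock libraries given above. In resistant birds on day 5, the transcripts called between susceptible and mock birds had median log2 fold changes against mock of 0.53 for the higher and -0.25 for the lower set, with 97.0% and 98.0% in the same direction. Both comparisons use the same mock libraries, which also selected the sets, so part of this agreement is built in. In simulated groups without any difference, sets of the same size with the smallest p had 87.2% and 84.2% in the same direction, with medians of 0.33 and -0.27. Over all transcripts, 82.4% went in the same direction, and 69.3% in the simulation. The simulation held no gradient among libraries, which shared mock libraries would carry into both comparisons. It may therefore understate the agreement that is built in. Across transcripts, the fold changes of susceptible and resistant birds against mock correlated with r = 0.70 on day 5, where simulated groups without any difference gave 0.581; the covariances were 0.308 and 0.125. On day 1 the correlation was 0.721 against 0.577, and the covariances were 0.138 and 0.116. The mock libraries were then divided, with 1 for one comparison and 2 for the other. Over the 6 divisions of day 5 the correlation was 0.296 on average (-0.151 to 0.531) and the covariance 0.143 (-0.075 to 0.30). The share of all transcripts going in the same direction was then 62.5% on average (41.6 to 75.3%). On day 1 the correlation was 0.077 (-0.249 to 0.281), the covariance 0.015 (-0.083 to 0.071) and that share 52.6% (35.6 to 64.0%). These depend on single mock libraries, and part of the excess may come from the shared controls.

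Whether susceptible and resistant birds differed was tested directly. On day 5, 4 transcripts passed, 1 higher and 3 lower in susceptible birds, and 3508 were at an unadjusted p under 0.05 (27.7%). The higher one was at 13.1 ± 8.92 CPM in susceptible and 1.20 ± 0.41 CPM in resistant birds (SD, n = 4 each), a log2 fold change of 3.44 ± 0.60 (SE, adjusted p = 0.0447). The lower ones had log2 fold changes of -1.51, -1.11 and -0.79. Values did not overlap for 1954 transcripts (15.4%), where splits of the libraries give 2.86% on average. The spread of this share over splits was not computed. DESeq2 called 1301 transcripts and limma-voom with sample quality weights 1. No low-count filter, a fit of the compared groups only and the replicate number as a block each gave 0, with 3740, 3417 and 3359 at an unadjusted p under 0.05. The higher transcript then had log2 fold changes of 3.43, 3.44 and 3.28 (adjusted p = 0.058, 0.0985 and 0.0828). It and the lower ones at -1.51 and -1.11 had 56 alternatives with an adjusted p. Of these, 25 kept the call, 31 lost it and 0 reversed. Leaving out single libraries gave 0 to 281, with 0 without resistant replicate 2 or 4 or susceptible replicate 2 or 4. On day 1 no transcript passed in edgeR or either other tool, with 166 at an unadjusted p under 0.05.

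Between the days, no transcript passed in edgeR in mock, resistant or susceptible birds, with 209, 386 and 1966 at an unadjusted p under 0.05. DESeq2 called 0, 5 and 111, and limma-voom with sample quality weights 52, 1 and 2. No transcript passed in edgeR when the within-day differences were compared between the days. The counts at an unadjusted p under 0.05 were 1613 for susceptible against mock, 237 for resistant against mock and 891 for susceptible against resistant birds. DESeq2 called 10, 1 and 0, and limma-voom with sample quality weights 83, 11 and 0. The larger count of day 5 was therefore not shown by edgeR to differ from that of day 1 for any single transcript.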

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

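The tests of reads assigned to no transcript were chosen after the values were seen. In 52 groups of 4 libraries examined over 13 measures, 5 held a library far from the others of its group. The limit used passes about 1 in 20 groups of normally distributed values. CPM and depth need not be so distributed, and the transcripts were picked from these data, so that rate may not hold here. ENSGALT00000025427 stood at 287 CPM in susceptible replicate 4 of day 5, against 1.72 to 5.49 CPM in the other libraries of that group, and at 6.38 CPM in resistant replicate 2 of day 1, against 0.492 to 1.31. ENSGALT00000015790 stood at 49.9 CPM in resistant replicate 1 of day 5, against 2.60 to 6.81, and at 54.1 CPM in susceptible replicate 1 of day 1, against 40.7 to 42.8. Resistant replicate 3 of day 5 had 17337896 reads on transcripts, against 10359676 to 11464633 in the other libraries of its group.

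Reads assigned to no transcript, which no comparison of the report uses, made up 23.6% ± 1.71 of counts in susceptible birds of day 5 (SD, n = 4), against 19.1% ± 0.44 in mock birds (n = 3) and 20.4% ± 2.32 in resistant birds (n = 4). All 4 susceptible libraries lay above the 3 mock libraries, with an exact permutation p of 0.0286, the smallest that 4 against 3 can give, and 0.129 after adjustment. The gradient among birds is argued against: within groups the share changed by -0.357 percentage points per unit of the gradient, where 2.41 would be needed. Sequencing depth is argued against too, with -0.679 percentage points per doubling within groups where -13.9 would be needed. Reads from DNA or unspliced RNA stay open: they could raise the number of annotated transcripts detected at equal depth, which was higher by 683 in susceptible than in mock birds, but transcription of more of these would raise it too. Reads from transcripts missing in the annotation were not tested.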

How the results depend on the processing

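The thinned, abundant-transcript, gradient and 2-library alternatives were chosen after seeing the data. For susceptible against mock birds on day 5, RLE scaling (3478), DESeq2 (4369), no filter (3042), the stricter filter (2888), the compared groups alone (2475), thinning (3229) and removal of the 10 most abundant transcripts (3420) stayed within 1.5 times of 3426. limma-voom with sample quality weights gave 6877, the gradient as a covariate 178, and removal of mock replicate 2 and susceptible replicate 2 gave 0. Leaving out single libraries gave 655 (without mock replicate 2) to 4158, with 1129 without mock replicate 3 and 1063 without susceptible replicate 2; the share of higher transcripts among the calls was 32.4% without mock replicate 3, against 50.1%. For susceptible against resistant birds on day 5, where 4 passed, DESeq2 gave 1301, limma-voom 1, thinning 2, and no filter, the compared groups alone and the 2-library removal 0 each; leaving out single libraries gave 0 to 281.

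In comparisons with 0 calls, DESeq2 gave 24 for susceptible against mock on day 1, 5 between days in resistant and 111 in susceptible birds, 10 for the by-day difference of susceptible against mock and 1 for that of resistant against mock. limma-voom gave 1210 and 1139 for susceptible and resistant against mock on day 1, 716 for resistant against mock on day 5, 52, 1 and 2 between days in mock, resistant and susceptible birds, and 83 and 11 for the by-day differences of susceptible and resistant against mock. Its library weights ran from 0.238 (mock replicate 1 of day 1) to 7.83 (mock replicate 3 of day 5). The compared groups alone gave 1 for susceptible against mock on day 1 and 1 between days in susceptible birds, and the gradient gave 4 and 1. Leaving out single libraries gave 0 to 1 for susceptible against mock on day 1, 0 to 34 between days in susceptible birds (34 without susceptible replicate 1 of day 5) and 0 in the other comparisons. Except where a construction explains it (fewer libraries or another set of transcripts), the cause was not tested.

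With the replicate number as a block, 3007 transcripts were called between susceptible and mock birds on day 5 and 0 between susceptible and resistant birds. The numbers were not shown to pair the samples: 20 of 51 pairs with the same number had deviations correlated over 0.1 (range -0.43 to 0.63), and 8 of 22 libraries correlated best with one of their own number. The mean r was 0.042 for pairs with the same number and -0.014 for the 150 pairs with different numbers. This difference was not tested, so a small effect shared by libraries of a number is not excluded. The 4 named transcripts had 71 alternatives with an adjusted p: 58 kept the call, 13 lost it (8 of them for ENSGALT00000025427) and 0 reversed; DESeq2 gave no p for ENSGALT00000025427. The 24 gene lists were not run. What depth limits was not separated from spread and library number. The simulation recovered 24% of 2-fold changes for susceptible against mock birds on day 5. Few transcripts were changed in it, so that share is not the sensitivity of the real test.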

Other observations

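Except for the split test with the gradient as a covariate, whose outcome was predicted before it was run, the tests in this part, and the limits by which they were read, were chosen after the results were seen. That split test replaced an earlier limit on the number of calls kept with the covariate, chosen after 148 kept calls were seen, under which the gradient as the whole cause had been excluded. More transcripts were detected in susceptible birds of day 5 than in the other groups of that day when every library was thinned to 7199071 reads: 14776 ± 138 (SD, n = 4), against 14092 ± 103 in mock (n = 3) and 14314 ± 260 in resistant birds (n = 4). All 4 susceptible libraries lay above every mock and every resistant library of that day. The exact permutation p was 0.0286 in each case, the smallest possible for these sizes, and 0.0857 after adjustment.

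The main gradient among birds within groups was compared with the day 5 difference. Its loadings were taken from 15 libraries outside that comparison, but the compared libraries helped to set its sign. The loadings correlated with the log2 fold changes of susceptible against mock birds across transcripts with r = 0.674. A loading of the matching sign was found for 89.8% of the higher and 92.5% of the lower transcripts. Splits of the same libraries came as far: in either direction, and with the real split included, 4 of 35 gave an r as large (exact permutation p = 0.114, highest other 0.713), and 10 and 7 of 35 gave shares as large for sets of the same size with the smallest p. The agreement is therefore not shown to be particular to susceptible against mock birds. Within groups over 22 libraries the gradient score correlated with the number of transcripts detected at equal depth (r = 0.695, permutation p = 0.00266; rho = 0.655, p = 0.00238), with the share of ambiguous reads (r = 0.834, p = 0.00014; rho = 0.836, p = 0.00014) and, negatively, with the share of reads in the 10 most abundant transcripts (r = -0.623, p = 0.0184; rho = -0.692, p = 0.00588). Over all libraries the r was 0.803, 0.624 and -0.707 in that order, and 0.711, 0.457 and -0.615 without the 2 farthest libraries. Of 6 relations computed, these 3 passed after adjustment (p for r of 0.00798, 0.00084 and 0.0368), and those with reads assigned to no transcript, reads with more than 1 alignment and depth did not (0.321, 0.321 and 0.0806). The number of transcripts detected and the share of each library's own 10 most abundant come from the same counts as the gradient score. Part of these 2 relations may therefore be built in.

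The 3426 transcripts called between susceptible and mock birds on day 5 were weighed against technical explanations. A chance division of the libraries stays open. Only the real split, 1 of 35, gave as many calls, with 509 in the highest other. That share is the smallest the test can give and was not adjusted over the comparisons. Elsewhere, where the real split had 0 calls, single other splits gave many. They gave 1335 for susceptible against mock birds on day 1 and 1363 for resistant against mock birds on day 5. For the by-day difference of resistant against mock birds, 1 gave 2661. Unequal depth is argued against, since 3229 were called at equal depth. A gradient among birds may account for much of the count: 3278 of the calls ended with it as a covariate, and the median log2 fold change fell from 1.54 to 0.90 (median SE 0.44 and 0.39) in the higher and from -0.86 to -0.34 (0.23 and 0.18) in the lower set. The libraries that define it came from resistant birds of both days and susceptible and mock birds of day 1. Mock libraries of day 5, which did not define it, scored from -2.08 to 0.21. The difference of mock replicate 1 of day 1 from replicates 2 and 3 correlated with the day 5 fold changes with r = 0.632. With the real split included, 2 of 35 splits came as far (exact permutation p = 0.0571). The gradient is therefore not shown to be independent of infection. As the whole cause it stays open, since with the covariate 2 of 35 splits gave as many calls as the real 178 and the highest other gave 406, although that split moved only susceptible replicate 1 to the mock side and the real split had the most transcripts at an unadjusted p under 0.05 (3035, against 2887). As the only difference between the groups it is argued against by ambiguous reads, which fit more than 1 feature and were counted for none. Their share may itself follow which transcripts are expressed. It rose with the gradient within groups, which predicts a share higher by 0.597 percentage points in susceptible than in mock birds of day 5. The share was 5.22% in susceptible and 5.30% in mock birds. Of reads on transcripts plus ambiguous reads, the share was higher in susceptible birds by 0.366, where the gradient predicts 0.726. At an equal gradient score the differences, susceptible minus mock, were -0.678 ± 0.187 percentage points (SE) of all counts and -0.361 ± 0.160 of reads on transcripts plus ambiguous reads, each more than 2 SE from 0. Such a further difference does not say what moved the transcripts, so it leaves the gradient open as the whole cause of the calls. A response to infection along the same gradient, which the covariate would remove, also stays open.

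Mock replicate 1 of day 1 had a gradient score of 1.00, against -0.78 and -1.38 in the other mock libraries of that day, and 60957310 reads. Its depth is argued against as the cause, since thinned to the smallest library it scored 1.07. A mislabelled library cannot be told apart from variation between birds, because only 5 of 22 libraries correlated best with their own group.

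For the other comparisons, chance was judged by splits of the same libraries. For susceptible against resistant birds on day 5, 1 of 35 splits gave as many as 4 calls, the real one, and the highest other gave 0. Where the real split had 0 calls, all 35 splits, or all 40 drawn for the by-day differences, necessarily gave as many, so the count of calls decides nothing about chance there. The highest other counts were 1335, 0 and 1 for susceptible against mock, resistant against mock and susceptible against resistant birds on day 1, 1363 for resistant against mock birds on day 5, and 1 and 1 between days in resistant and susceptible birds. For the by-day differences of susceptible against mock, resistant against mock and susceptible against resistant birds they were 3, 2661 and 1. At an unadjusted p under 0.05, the real split between days in susceptible birds had the most transcripts of 35 splits, 1966 against 1615 in the highest other. In the other comparisons, in the order above, 10, 22, 29, 17 and 18 of 35 splits had as many as the real one (614, 286, 166, 382 and 386 transcripts; highest other 4225, 3237, 2424, 4129 and 3079). For the by-day differences these were 2, 29 and 5 of 40 (1613, 237 and 891; highest other 3928, 4853 and 2134). Between days in mock birds there were 10 splits, too few for a share under 0.05, with 0 calls in the real split and 0 in the highest other, and 209 against 2930 at an unadjusted p under 0.05. Splits with 1335, 1363 and 2661 calls, where the real count was 0, point to a structure of the libraries other than their groups.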
